A study of Mus musculus with 2 samples.

How the data were processed

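Small RNA of c-Kit+ Sca1+ Lineage- cells, the bone marrow fraction that holds hematopoietic stem cells and early progenitors, was measured on 2 Agilent 1-colour mouse miRNA arrays. One array held RNA of cells with intact Tif1b alleles (WT) and one RNA of cells whose Tif1b alleles carry loxP sites (KO), both with a CreERT transgene, per the labels. Tif1b (Trim28, KAP1) is a corepressor that silences retroelements and many genes through zinc finger proteins. Per the labels' protocols, total RNA was isolated with a Qiagen miRNeasy kit and 100 ng was labelled with Cyanine 3. When and how recombination was induced is not given in the sources used here.

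The deposited array files hold spot intensities on a linear scale, extracted with Agilent Feature Extraction 10.7.3, per the submitters' processing notes. Per the file headers, the software subtracted a fitted additive spatial trend with its further background correction switched off, and no normalization between arrays is recorded. Both arrays came from 1 slide and 1 scan, so no slide or scan difference separates the groups. Each array carried 52044 spots, of which 49880 belonged to 3105 probes for 1247 mouse miRNAs, with 40 spots per miRNA. The deposited value table of the series was compared with the arrays: in both columns all 1268 rows matched the software's total gene signal intensity within 0.1%, unlogged, uncentred and unscaled, with a floor of 0.1 that was also the median of each column.

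For each probe, the mean processed signal of its spots was taken, leaving out spots the software had marked as outliers (5.16% on the WT array and 4.59% on the KO array). A probe counted as measured on an array when more than 50% of its remaining spots were marked well above background. Probe means were divided by the 75th percentile over the 113 probes measured on both arrays and put on the log2 scale. This percentile was 487 for WT and 213 for KO. The difference is KO minus WT, and a miRNA's value is the median over its probes measured on both arrays. The spot SD of a difference is the SD of the log2 ratio of KO to WT over spot positions, combined over the measured probes. It is technical and says nothing about animals. Where a miRNA was measured on 1 array only, a lower bound was computed as the bright signal over the higher of the dim array's lowest measured probe signal and the dim probe's own signal, after scaling. No fold is given where that bound was under 1.

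With 1 array per group no test between genotypes is possible. The number of arrays limits the precision, and neither p-values nor errors across animals are given. Counts of miRNAs with a difference of at least 2-fold describe these arrays. The median of each miRNA list with at least 3 measured members was placed among 10000 random lists of the same size, drawn within 3 bands of mean level, again as a description. The 18 lists, the rule for named miRNAs and 13 alternatives were set before the data were examined, and 4 alternatives were added afterwards. Named miRNAs are the up to 15 largest differences in each direction with all measured probes in 1 direction and a size above 2 spot SDs. To these come the up to 8 largest bounds per direction and the up to 4 largest differences in each list. The condition on direction is empty for a miRNA with 1 measured probe. Of the 72 miRNAs measured on both arrays, 41 had more than 1. The spot noise within an array was measured by splitting each probe's spots at random 100 times and comparing the parts in the same way as the arrays.

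Alternatives covered the scaling (75th percentile over all probes, none, quantile, median, positive controls), the background correction (limma's normexp with offset 50), the software's total gene signal, the value table, the filter on dim probes (other filters, or none), the probe and spot summaries, outlier spots, pairing spots by position and leaving out rows above 320. With no filter, the alternative set beforehand was computed with a floor: scaled signals on either array below the lowest measured KO signal were raised to it, which also replaces measured WT signals and sets probes that are dim on both arrays to a difference of 0. An added one used all probes with a signal above 0 on both arrays at their own values. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1.

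The procedure was tested on a simulated KO over WT comparison with a dimmer KO array and known changes in 24 miRNAs, 6 at each size. Of the miRNAs measured on both simulated arrays, 6 of 6 with a true log2 change of 3 and 2 of 2 with -3 were found at least 2-fold changed in the right direction, as were 3 of 6 with 1.5 and 1 of 1 with -1.5. Most simulated decreases were thus not measured on both arrays: only 2 of 6 at -3 and 1 of 6 at -1.5 were. Of 63 unchanged miRNAs, 1 passed the same size. Apart from the dimming and the known changes, both simulated arrays were built from the same WT probe means with independent spot noise. Other differences between arrays, labellings and animals were thus left out of that count. The scaling moved the unchanged miRNAs by -0.42, because bright miRNAs had been raised, so list medians and the counts at 2-fold are also given relative to the median miRNA. In the simulation of gene list medians over 72 miRNAs, 2 of 100 unshifted lists of 9 and 90 of 100 lists shifted by 1 lay outside the central 95% of random lists. The simulated differences were independent, so these shares do not carry over to lists whose members share precursors or near-identical sequences.

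Probe positions are those listed in the array files. The file headers name the mm9 build, while the files list coordinates of more than 1 build for a probe. Printed here are those that lie inside a miRNA gene of the GRCm38.p6 gene table, which held for 46 of 48 named miRNAs. Names of overlapping genes come from that table. The array carries no probe for Tif1b mRNA, so the knockout itself was not checked. All miRNA names on the array were of mouse, so the list of viral miRNAs had 0 members.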

Results

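miRNA levels were compared between c-Kit+ Sca1+ Lineage- bone marrow cells of 1 WT and 1 Tif1b KO sample, to describe the miRNAs of stem and progenitor cells labelled as deficient in this corepressor. The array has no probe for it, so its loss was not checked. There was 1 array per genotype and no replicate, so each difference describes these arrays. The KO array was dimmer. Of its miRNA spots, 2510 were well above background against 3308 on the WT array, and the mean processed signal was 9.14 against 21.9. On the WT array 100 miRNAs were measured and on the KO array 78. Of the 1247 miRNAs, 72 were measured on both arrays, 28 on WT only, 6 on KO only and 1141 on neither.

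miR-223-3p is a miRNA abundant in granulocytes and monocytes. Of the miRNAs measured on both arrays, it had by far the lowest KO minus WT difference. The highest differences were those of miR-193b-3p, miR-6368 and miR-155-5p. Among the 72 miRNAs measured on both arrays, 10 were at least 2-fold higher on the KO array, 10 at least 2-fold lower and 52 within 2-fold. The median difference was 0.30 on the log2 scale, with quartiles of -0.17 and 0.65. This balance depended on the scaling. The 75th percentile of the KO array was 0.437 of that of the WT array, and without scaling the median difference was -0.89, with 1 miRNA at least 2-fold higher and 32 at least 2-fold lower. Differences relative to the median miRNA do not depend on that factor, and by them 6 miRNAs were at least 2-fold higher and 10 at least 2-fold lower. The 4 that then lay under 2-fold were miR-5126, miR-196b-5p, let-7c-5p and let-7b-5p. The control probes did not settle the factor, with KO signals from 0.407 of WT (the bright corner probe) to 1.02. Splitting the spots of 1 array at random gave a median of 0 miRNAs at least 2-fold apart, and at most 1 on the WT array and 2 on the KO array. This split leaves out differences between arrays, labellings and animals, so it does not measure the noise of the KO minus WT differences.

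**Figure D1:**
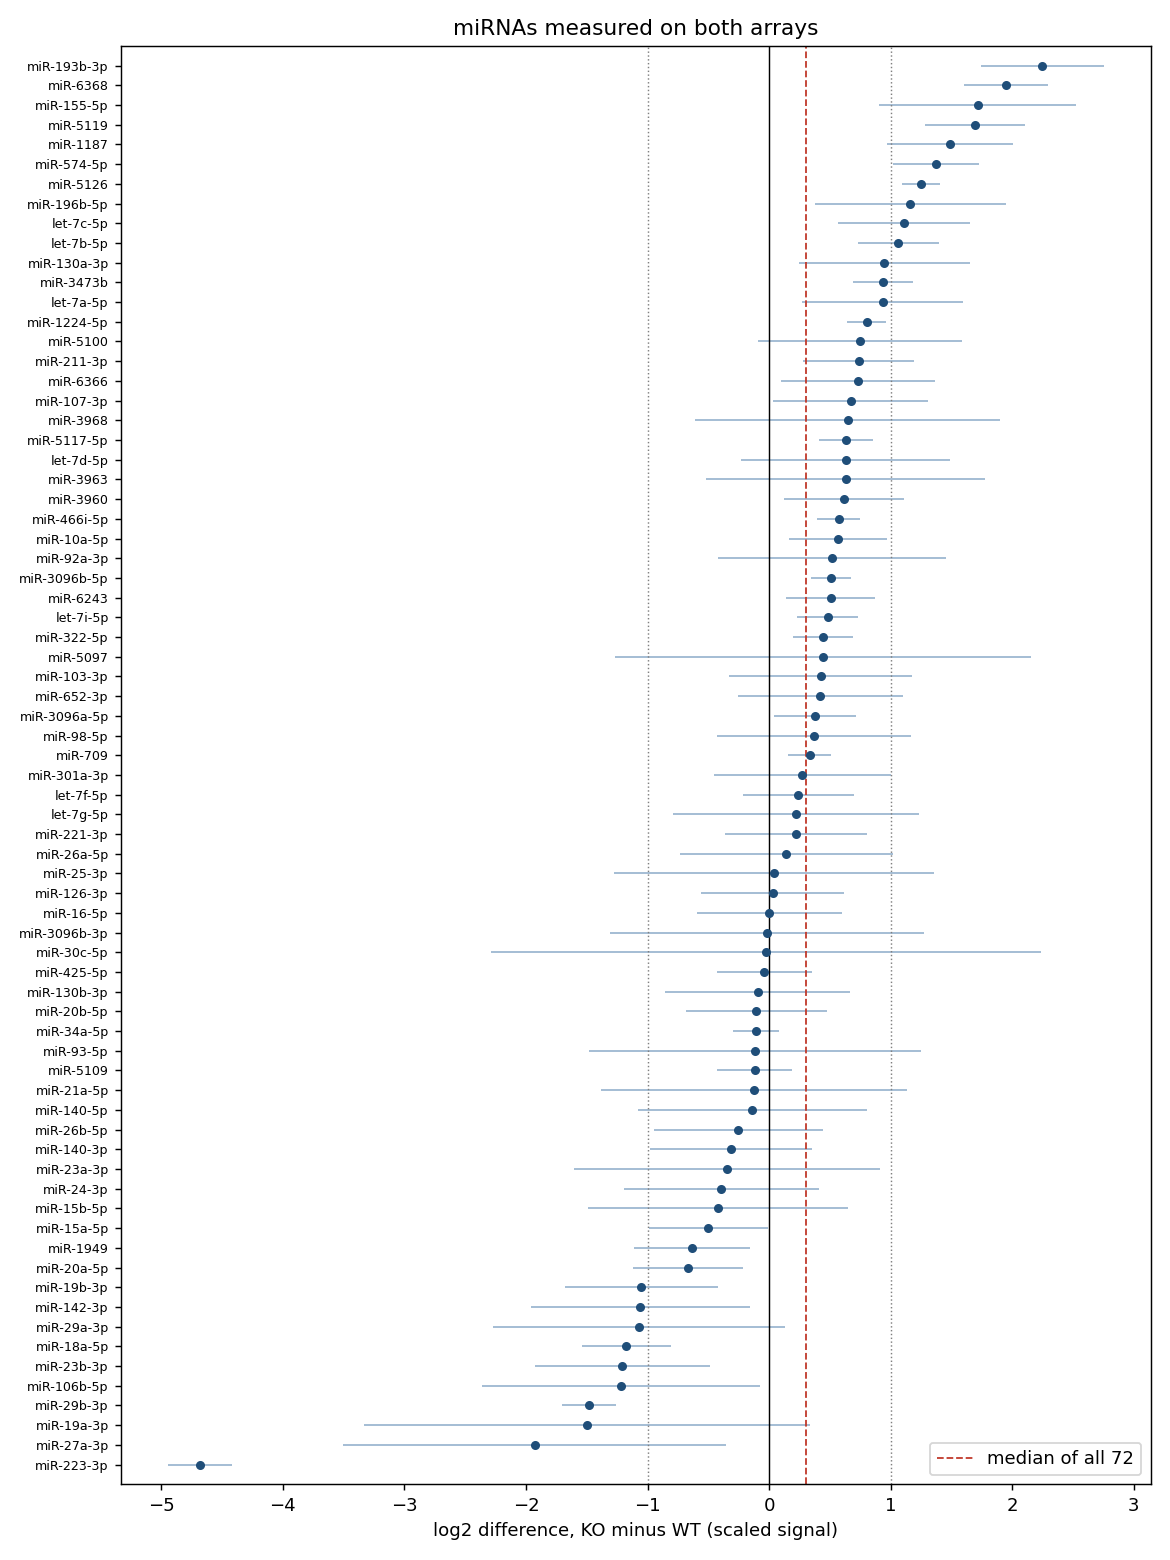
Log2 difference of the scaled signal, KO minus WT, for the 72 miRNAs measured on both arrays; bars are 1 spot SD, dotted lines mark 2-fold, and the dashed line is the median of 0.30. miR-223-3p lies alone at -4.68, and miR-193b-3p is the highest at 2.25; without scaling every point moves down by the same amount, and points between 0 and 1.19 fall below 0.

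The signal of miR-223-3p was 3726 on the WT array and 63.6 on the KO array. Its scaled difference was -4.68 (spot SD 0.26 over 17 spot positions), which is 25.6-fold. It was at least 2-fold lower under every alternative, and with normexp it was the only one of the 10 that was. The probe, TGGGGTATTTGACAAACTGAC, lies in Mir223 on chromosome X at 96242885 to 96242905 (GRCm38, plus strand), inside the noncoding gene F630028O10Rik. All 17 spot positions were lower on the KO array than the scaling ratio alone would give. A second probe had 823 on the WT array and 15.6 on the KO array, where it was not well above background. The other decreases that exceeded 2 spot SDs were miR-29b-3p at -1.48 (spot SD 0.22) and miR-18a-5p at -1.17 (spot SD 0.37). Relative to the median miRNA, miR-23b-3p (-1.51), miR-19b-3p (-1.35), miR-20a-5p (-0.97) and miR-34a-5p (-0.41) exceeded 2 spot SDs as well. miR-29b-3p was within 2-fold with normexp (-0.82) and with no filter and a floor (-0.74). miR-29b is known to target DNA methyltransferases and extracellular matrix genes. Its probe AACACTGATTTCAAATGGTGC matches Mir29b-2 on chromosome 1 at 195037093 to 195037113 and Mir29b-1 on chromosome 6 at 31063071 to 31063091, so the signal cannot be assigned to either copy.

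Among the increases, 14 miRNAs exceeded 2 spot SDs, a count that depended on the scaling. Relative to the median miRNA, miR-155-5p (1.41) and let-7c-5p (0.81) did not exceed 2 spot SDs. The same held for miR-5117-5p (0.33), miR-466i-5p (0.27) and miR-3096b-5p (0.21). miR-193b-3p is known to restrain cytokine signalling in hematopoietic stem cells. It was at 22.4 on the WT array and 46.6 on the KO array, a scaled difference of 2.25 (spot SD 0.50) or 4.75-fold. This value rests on 1 probe, with a WT signal near the lowest measured WT probe (17.7). The second probe of miR-193b-3p was measured on neither array. Its probe AGCGGGACTTTGTGGGC lies in Mir193b on chromosome 16 at 13449575 to 13449591. miR-6368 differed by 1.95 (spot SD 0.35), and its probe lies in Mir6368 on chromosome 13 within 2610307P16Rik. miR-155-5p, a regulator of myeloid expansion and lymphocyte activation, was at 94.1 on the WT array and 135 on the KO array, a difference of 1.72 (spot SD 0.81) or 3.28-fold. miR-155-5p likewise rests on 1 probe, with the second, at 14.2 on WT and 16.9 on KO, measured on neither array. Its probe ACCCCTATCACAATTAGC lies in Mir155 on chromosome 16 at 84714148 to 84714165, inside the host transcript Mir155hg. miR-5119 differed by 1.69, miR-1187 by 1.49, miR-574-5p by 1.37 and miR-5126 by 1.25. These 7 miRNAs were brighter on the KO array before scaling as well, by the median over their probes, and no other miRNA measured on both arrays was, but only miR-193b-3p was at least 2-fold higher before scaling. miR-574-5p was at 0.92 with the stricter filter. With no filter and a floor, miR-193b-3p was at 0.57, miR-155-5p at 0.86, miR-574-5p at 0.64, miR-1187 at 0.17 and miR-5119 at 0. That floor pulls differences of dim probes to 0 by construction, and without it these miRNAs were at least 2-fold higher. Probes of miR-1187 and miR-574-5p carry a run of alternating A and C, a pattern described under other observations. let-7c-5p (1.11) and let-7b-5p (1.06) passed 2-fold with the scaling and were -0.083 and -0.13 without it. Both were under 2-fold also with normexp (0.92 and 0.86) and the stricter filter (0.90 and 0.87), and let-7b-5p with quantile normalization (0.98) and the brightest probe (0.92). miR-3473b, miR-1224-5p, miR-5117-5p, miR-466i-5p and miR-3096b-5p lay between 0.51 and 0.94, and all 5 were below 0 without scaling.

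Of the miRNAs measured on 1 array only, those seen on KO only were miR-3082-5p, at least 4.09-fold higher, miR-467f (at least 3.37-fold), miR-877-3p (3.25), miR-466h-3p (3.17), miR-466f-3p (3.06) and miR-466i-3p (2.97). All 6 were dim, with KO signals of 23.0 to 31.9 against a lowest measured KO probe of 21.1. Probes of all but miR-877-3p carry a run of alternating bases, a pattern described under other observations. The bounds of these 6 miRNAs depended on the processing, and without scaling they were 1.30-fold to 1.79-fold. By total gene signal, a different summary with its own detection call, they were 7.44-fold to 18.4-fold for the 5 with a value. With the stricter filter none of the 6 had a bound. The probe for miR-466f-3p matches copies of its gene inside Sfmbt2 on chromosome 2, and that for miR-466h-3p lies inside the same gene. Of the 28 seen on WT only, miR-27b-3p was at least 2.42-fold and miR-148a-3p at least 2.05-fold higher in WT. miR-30e-5p and miR-17-3p followed with bounds of 1.49-fold each and miR-378b with 1.34. The bounds of miR-3072-5p and miR-30d-5p were 1.01-fold and 1.00-fold, and the other 21 allowed no fold. With normexp the bound of miR-27b-3p was 1.07-fold and the other 6 allowed no fold. With the stricter filter the bound of miR-148a-3p was 1.13-fold. Without scaling the 7 bounds were 2.29-fold to 5.52-fold.

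On the list of miRNAs enriched in hematopoietic stem cells, the few members measured on both arrays stood high. Of the list's 31 miRNAs on the array, 7 were measured on both arrays: 3 were at least 2-fold higher, 1 at least 2-fold lower and 3 within 2-fold. Another 2, miR-99a-5p and miR-146b-5p, were measured on WT only, with no fold, and are left out of the list median and percentile. The remaining 22 were measured on neither array. No miRNA of miR-125a, miR-125b, miR-99b, miR-100 or let-7e was measured on either array, so the median and percentile do not describe the whole list. The members with the largest differences were miR-193b-3p (2.25), miR-155-5p (1.72), miR-196b-5p (1.16, spot SD 0.78) and miR-29a-3p (-1.07, spot SD 1.20). The list median was 0.95, or 0.64 above the median miRNA, at the 99.3 percentile of random lists. With normexp it was 0.38 above the median miRNA. Without scaling the list median was -0.25, and 1 of the 3 increases was still at least 2-fold. With no filter and a floor 0 of the 3 were, and with no filter and no floor all 3 were. miR-196b-5p was within 2-fold with normexp (0.95) and the stricter filter (0.92). miR-29a-3p was within 2-fold with quantile normalization (-0.88), normexp (-0.75), total gene signal (-0.63) and spots paired by position (-0.96). miR-196b-5p, encoded in the Hoxa cluster, and miR-10a-5p (0.57), whose probe lies within Hoxb3, were the measured members of the Hox-locus list, and without scaling they were at -0.032 and -0.63. miR-322-5p, the only measured member of its X-linked cluster, was at 0.44, or -0.75 without scaling.

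The myeloid list stood low. All 6 of its 17 miRNAs that were measured on both arrays lay below the median miRNA, and 3 were at least 2-fold lower. Besides miR-223-3p these were miR-27a-3p at -1.93 (spot SD 1.58) and miR-142-3p at -1.06 (spot SD 0.90), a miRNA shared by all blood lineages. miR-24-3p was at -0.39. The list median was -0.73, or -1.03 relative to the median miRNA, at the 3.59 percentile of random lists. Mir23a and Mir24-2 lie within 10 kb of Mir27a on chromosome 8, so miR-23a-3p, miR-27a-3p and miR-24-3p cannot be taken as independent members. Without miR-223-3p the other 5 had a median of -0.39. miR-142-3p was within 2-fold with normexp (-0.74), total gene signal (-0.59), quantile normalization (-0.89) and spots paired by position (-0.96), and miR-27a-3p was with normexp (-0.79).

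The miR-17-92 cluster and its paralogs, which promote proliferation of progenitors, were also low. Of 27 miRNAs, 9 were measured on both arrays, of which 4 were at least 2-fold lower and 5 within 2-fold. The 4 were miR-19a-3p, 2.83-fold lower (spot SD 1.84 on the log2 scale), miR-106b-5p at -1.22 (spot SD 1.15), miR-18a-5p at -1.17 and miR-19b-3p at -1.05 (spot SD 0.63). With normexp 0 of the 4 were at least 2-fold lower, with values of -0.45 to -0.84, and by total gene signal 1 was, miR-19a-3p at -1.01. Without rows above 320, miR-19b-3p was at -0.98. Only miR-92a-3p, at 0.51, lay above the median miRNA. The list median was -0.66, or -0.97 relative to the median miRNA, at the 1.74 percentile of random lists. The members share precursors and near-identical sequences, so they are not independent. The probe for miR-18a-5p lies in Mir18 on chromosome 14 at 115043871 to 115043889 and that for miR-19a-3p in Mir19a at 115044050 to 115044070.

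All 8 measured members of the let-7 family, which favours differentiation and differs within itself by few bases, were between 0.22 and 1.11, with miR-98-5p among them. let-7c-5p and let-7b-5p were at least 2-fold higher, and let-7a-5p (0.93) and let-7d-5p (0.63) were not; without scaling these 4 were below 0. The list median of 0.56 was 0.25 above the median miRNA, at the 90.3 percentile of random lists, and it was -0.64 without scaling. The miR-15/16 family had 4 measured members, all within 2-fold: miR-15a-5p (-0.50), miR-15b-5p (-0.42), miR-16-5p (0.00) and miR-322-5p (0.44). Its median of -0.21 lay at the 25.5 percentile, and it was 0.26 by total gene signal.

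**Figure D2:**
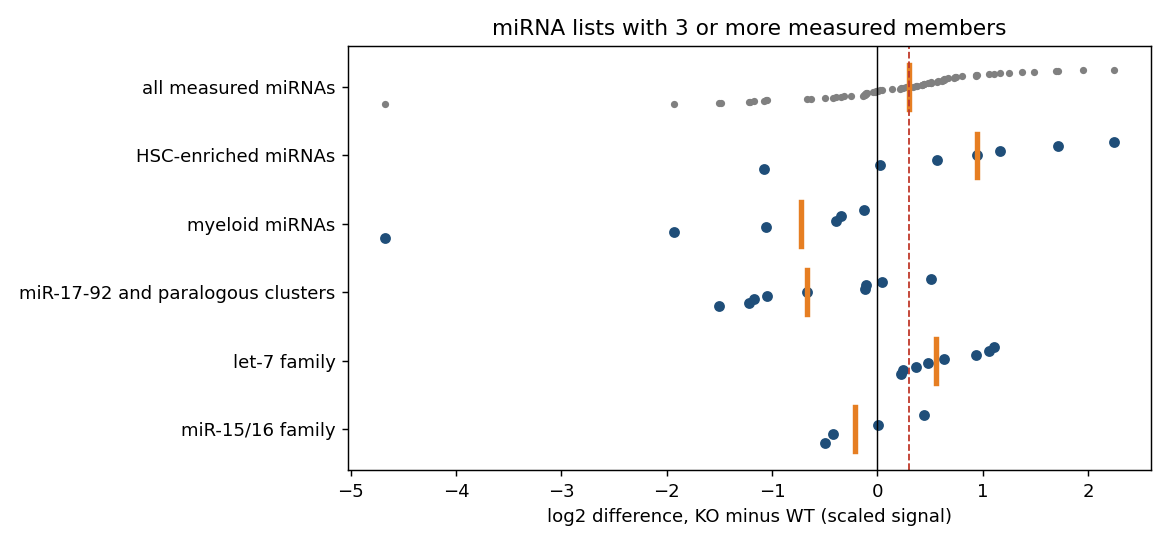
Log2 difference of the scaled signal, KO minus WT, of each measured miRNA (points) in the 5 lists with at least 3 measured members and in all 72 miRNAs, with list medians as vertical bars; the dashed line is the overall median. The myeloid (-0.73) and miR-17-92 (-0.66) medians lie left of the line, and the medians of the lists enriched in stem cells (0.95) and of let-7 (0.56) lie right of it but below 0 without scaling.

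Other lists had fewer than 3 measured members. Of the lymphoid list, miR-155-5p was measured on both arrays, and miR-181b-5p, miR-181c-5p and miR-181d-5p on WT only, with no fold. Of the inflammation-responsive list, miR-155-5p and miR-21a-5p (-0.12, or 0.32 by total gene signal) were measured on both arrays. Of the p53-responsive list, miR-107-3p was at 0.67 (-0.52 without scaling) and miR-34a-5p, a direct p53 target, at -0.11 (0.33 with normexp). In the families of miR-297, miR-466, miR-467 and miR-669, miR-466i-5p was at 0.57 (-0.62 without scaling), 4 members were measured on KO only and 56 of 61 on neither array. None of 99 miRNAs of the Dlk1-Dio3 imprinted cluster was measured on both arrays, and miR-3072-5p was measured on WT only. No miRNA of the other imprinted loci (10 on the array) or the pluripotency clusters (24) was measured on either array. The same held for markers of cells that a sort might carry along: 12 erythroid miRNAs, 13 of stromal, endothelial-wall and muscle cells, and 25 of epithelium, liver and brain.

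**Figure D3:**
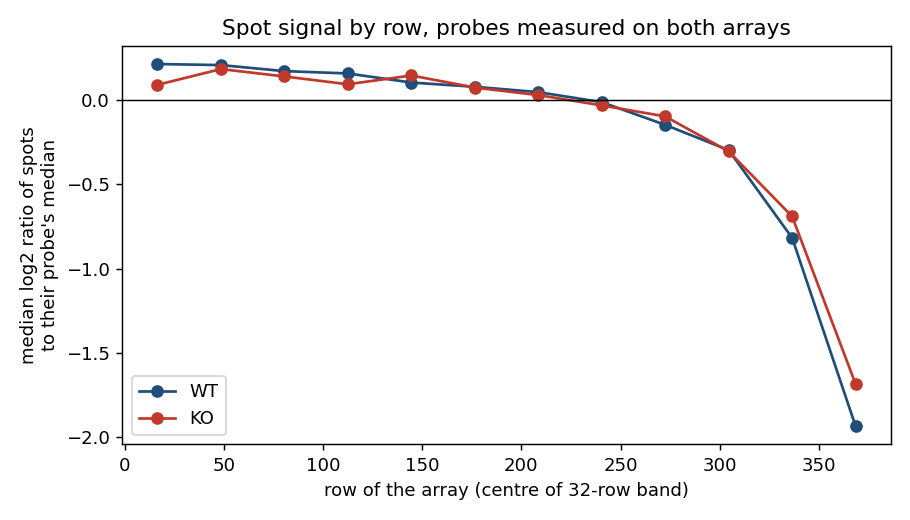
Median log2 ratio of spots to the median of their probe, by band of 32 rows, for probes measured on both arrays. The last band lay at -1.93 on the WT array and -1.68 on the KO array, a fall shared by both arrays.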

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

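Results were recomputed under 13 alternatives set before the data were examined and 4 chosen afterwards (pairing spots by position, leaving out rows above 320, scaling on positive controls, no filter without a floor), where an alternative gave a value; 61 values of named miRNAs could not be had, among them all bounds with no filter on dim probes, and list percentiles were not recomputed except as given under other observations. No paired analysis was possible because each genotype has 1 array. A list median counted as moved when it shifted by more than its own technical spread, the SD of the median with each member varied by its spot SD. Relative to the median miRNA, which 4 of the scalings cannot change, list medians kept their direction. With no filter on dim probes and a floor, the myeloid list moved to -0.39 (-1.03 as reported), miR-17-92 to -0.48 (-0.97) and let-7 to 0.56 (0.25). The floor pulls differences of dim probes to 0 by construction, and without it the myeloid list was at -1.07, miR-17-92 at -0.86 and let-7 at 0.55. By total gene signal and the value table let-7 moved to 0.51. It was lower with normexp (0.12) and the stricter filter (0.089), shifts within its technical spread of 0.24. The scaling set the direction of much else, and the cause was not tested. The 4 hur control probes behind the positive-control scaling were on KO at 0.696 to 1.02 of WT, while the control mr_1 (0.555) and the bright corner probe (0.407) lay nearer to the 0.437 used. In the order 75th percentile over all probes, no scaling, positive controls, the number at least 2-fold higher was 1, 1 and 2 (10 as reported) and the number lower 31, 32 and 25 (10 as reported). In the same order the median of all measured miRNAs was -0.79, -0.89 and -0.64 (0.30), the stem cell list -0.14, -0.25 and 0.0049 (0.95), the miR-17-92 list -1.76, -1.86 and -1.61 (-0.66), let-7 -0.53, -0.64 and -0.39 (0.56) and miR-15/16 -1.30, -1.40 and -1.15 (-0.21). The myeloid list was at -1.82, -1.92 and -1.67 (-0.73). Of 35 named miRNAs measured on both arrays, the sign turned for 12 over all probes, 14 without scaling, 11 with positive controls, 4 by total gene signal or the series value table and 1 with normexp (miR-34a-5p). It turned for miR-16-5p, at 0.0031 as reported, with other filters and summaries too. Among those at least 2-fold changed, signs turned for let-7b-5p (-0.027 over all probes, -0.13 without scaling), and without scaling for let-7c-5p (-0.083) and miR-196b-5p (-0.032). The total gene signal and the series value table each gave 29 higher and 5 lower, with medians of 0.58 for all miRNAs, 1.48 for the stem cell list, -0.21 for miR-17-92, 1.08 for let-7 and 0.26 for miR-15/16, whose sign turned. With normexp, whose offset shrinks differences of dim probes, 1 was lower and the median of all was 0.46. With no filter and a floor 4 were higher and the median of all was 0.00. With no filter and no floor, over 106 miRNAs of which 72 were measured on both arrays, 16 were higher and 24 lower, the median of all was 0.0075, and all 10 higher and 10 lower miRNAs reported were still at least 2-fold apart. The stem cell list was at 0.57 both ways. The strictest filter, which keeps fewer probes, left 45 miRNAs on both arrays and 22 on one, with 3 higher and 5 lower. For named miRNAs, 554 recomputed values moved by less than 1 spot SD and 201 by more, those with a turned sign included. Signal over background limits the rest: 1141 miRNAs were measured on neither array.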

Other observations

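The tests in this part and the miRNAs named in this paragraph were chosen after the results were seen. miR-23b-3p was at -1.21 (spot SD 0.72), miR-23a-3p at -0.35 and miR-24-3p at -0.39, or 0.059 by total gene signal. miR-27a-3p was at -1.93, and miR-27b-3p was measured on WT only. miR-29b-3p was at -1.48 and miR-29a-3p at -1.07, while miR-29c-3p was measured on WT only with no fold.

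The 19 measured miRNAs numbered 1000 or more had a median of 0.63, against 0.03 for the 53 with lower numbers, and 16 of the 19 lay above the overall median; their probes had a median GC content of 60% against 45.8%.

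The low miR-223-3p signal was set against 3 explanations. A KO array dimmer as a whole is argued against by the next lowest miRNA measured on both arrays. It was at -3.12 before scaling while miR-223-3p was at -5.87. This leaves out miRNAs measured on WT only, and many of the others could not have fallen as far and stayed measured on KO. A fault of 1 probe or a few spots is argued against by the second probe, which was not well above background on KO: its KO signal was at most 2.56% of its WT signal, an unscaled decrease of at least 39.1-fold. Fewer mature myeloid cells in the KO sort may contribute and cannot be told apart from lower expression within the sorted cells: the other 5 measured miRNAs of the myeloid list had a median of -0.39, all below the overall median, but these are also made by stem and progenitor cells, and the lineage depletion would remove mature cells. An effect of genotype stays open and untested with 1 array per group.

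The low miR-17-92 list was set against the GC content of its probes and spot position. Differences rose by 0.18 per 10% of probe GC, and the list's probes were no poorer in GC (51.3% against 46.2%). Removing the GC trend of the other miRNAs could thus hardly lift the list among random lists. Its median was then -0.84, at the 1.47 percentile. With spots paired by position the list lay at -1.04 relative to all measured miRNAs, at the 1.46 percentile. The percentiles treat members as independent, which they are not. The direction of the GC trend and the paired spots argue against a linear GC trend and spot position as the whole cause. Probe length, binding strength and cross-hybridization were not tested. A difference between the genotypes, or in the cycling of the sorted cells, remains a hypothesis that 1 array per group cannot test.

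Probes with a run of at least 8 bases of alternating A and C or G and T tended to be brighter on the KO array before scaling (17 of 17 miRNAs with G and T runs, 11 of 13 with A and C runs), though most lay near background and near-identical probes are not independent. These counts include the miRNAs that prompted the pattern. Of the 106 miRNAs measured on either array, 13 were brighter on KO before scaling. Such a run was carried by 7 of these 13 and by 8 of the 106. The 7 were miR-1187, miR-574-5p, miR-3082-5p, miR-467f, miR-466f-3p, miR-466h-3p and miR-466i-3p. An exception was miR-466i-5p, the only miRNA of the miR-297, miR-466, miR-467 and miR-669 families measured on both arrays, at -0.62 before scaling, where the median miRNA was at -0.89. More RNA carrying such repeats in the KO sample may contribute but stays open: outside the families, once the miRNAs that prompted the pattern are left out, 3 of 4 with such a run were brighter (75%, exact 95% interval 19.4% to 99.4%), against 33.2% of 1157 with runs of up to 5 bases. Higher expression of the families as such cannot be told apart: 5 of their 15 miRNAs with runs of up to 5 bases were brighter (33.3%, exact 95% interval 11.8% to 61.6%), but all lay near background and exclude nothing. With runs of 6 to 7 bases, 18 of 23 in the families and 9 of 22 outside were brighter.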
